A study of Mus musculus with 3 samples.

How the data were processed

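H3K4me1 was measured by ChIP-seq with an antibody against the modified histone in primary adipocytes of male C57BL/6J mice, in 1 wild-type (WT) and 1 adipocyte-specific Lonp1 knockout (AKO) library, with 1 input library. Groups were taken from the genotype and antibody labels. The input's title names it as the control of the AKO library while its genotype label says wild type. Per the file headers, the same input was used for both peak calls. The input has no peak list and enters only as the background in the authors' values. How many mice and which fat depot each library came from is not given in the sources used here.

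Per the submitters' processing notes, reads were handled with bcl2fastq, FastQC 0.11.3, Bowtie2 2.2.5 and MACS2 2.2.1 on mm10. The file headers name MACS 2.1.1.20160309 instead. Per the file headers, each ChIP library was compared with the input in narrow-peak mode at a q-value cutoff of 0.05, from single-end tags of 150 bp, with at most 1 tag kept per position and with no pooling of libraries. H3K4me1 forms broad domains, which narrow mode splits into several peaks, so peak numbers and widths depend on that choice. Tags numbered 19380523 in WT and 18656432 in AKO before and 15015805 and 14733950 after removal of duplicates (redundant tags 23% and 21%), against 9537585 for the input. The deposited values per peak are the pileup signal at the summit, the fold enrichment over local background, and −log10 p and −log10 q, all made by the authors with MACS. Per the file headers, the larger dataset was scaled to the smaller, so pileup in both lists is in units of the input's tag number. Every pileup value divided by the scale factor of its library (0.635 for WT and 0.647 for AKO) was a whole number within 0.02, which gives the number of fragments at each summit. Deposited positions and lengths were used as 1-based mm10 coordinates.

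Gene positions came from a RefSeq table of GRCm38.p6, the assembly named mm10, and all 467 distinct genes of the fixed lists matched by symbol. This table has no strand, exons or sequence. The window of 20 kb around the 5′ end of each gene, set before the data were examined, was therefore replaced by the gene body with 10 kb on both sides. Peaks were placed relative to either gene end and not to promoters, exons or introns, and motif counts were not run. Longer genes have longer windows, so differences in kb are larger at long genes.

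Overlaps were computed with bedtools 2.31.1 and the rest with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A peak was shared if it overlapped a peak of the other list by at least 1 bp. Shares carry Wilson 95% intervals. Chance overlap was taken from 100 circular shifts along each chromosome. For each of 21631 protein-coding genes the length covered by peaks was summed in its window. A gene was called lower in AKO if the WT to AKO ratio was above 2 and the difference at least 2 kb, and higher in the reverse case. This rule stands in for a test, since 1 library per genotype allows none. The median AKO minus WT coverage of each list was placed among 10000 random lists of the same size matched on mean coverage in 20 bins, which describes these libraries only. Peaks on unplaced contigs and the Y chromosome, 8 in WT and 6 in AKO, were left out of gene, region and chromosome counts. Gene density was counted in 5 Mb bins with at least 40 peaks over both lists, and intervals came from 1000 bootstrap resamples of bins.

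The 18 lists cover thermogenesis, adipocyte identity, fatty acid oxidation, the TCA cycle, oxidative phosphorylation, mitochondrial proteostasis, the integrated stress response, extracellular matrix, progenitors, macrophages, inflammation, lymphocytes, endothelium, skeletal muscle, other tissues, housekeeping, histone methylation enzymes and lipolysis. Of the thermogenic genes, 3 are also in another list. Genes named were the 14 fixed genes, the 10 genes with the largest difference in each direction with non-overlapping windows, the extreme members of each list, the thermogenic genes that met the rule of size, and the 5 strongest peaks of each library over 1 kb from the other's, with the nearest gene. Other list members that met the rule of size were named after their values were seen. Some genes that these rules name are not reported here. Lists, rules and most alternatives were set before the data were examined. On simulated data with 20000 genes, 99 of 100 lists of 40 genes with a planted deficit of 1 kb lay below the 5th percentile, and 2 of 100 lists without one did. Every simulated gene had coverage and the genes were independent. Among the real genes, 6707 of 21631 have no peak and neighbouring windows overlap, so these rates do not carry over to the real lists. Alternatives covered stricter peaks, lists of equal number or equal covered length (the strongest peaks, up to 50% of the shorter list), joined peaks, other overlaps, other windows and other matching.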

Results

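Histone H3 monomethylated at lysine 4 (H3K4me1), a mark of enhancers, was mapped by chromatin immunoprecipitation and sequencing in primary adipocytes of male C57BL/6J mice. The first library came from wild-type animals (WT), the second from mice lacking LONP1, the mitochondrial matrix protease Lon, in adipocytes only (AKO, for adipocyte knockout). An input library without antibody served as background for both. The WT library held 15015805 tags and the AKO library 14733950 tags after duplicates were removed, and the input held 9537585. There was 1 library per genotype, so no spread between replicates exists. No p-value for genotype is given, and every difference below is a difference between these 2 libraries. Wilson intervals cover counting error only, bootstrap intervals cover spread within these libraries, and none covers spread between animals. Genes are called lower or higher in AKO by a rule of size and not by a test.

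The first comparison asks how much of the genome carried the mark in each genotype. The AKO library had fewer and narrower H3K4me1 peaks than the WT library. The authors' lists held 72040 WT peaks and 62361 AKO peaks, an AKO to WT ratio of 0.866. The peaks covered 60.2 Mb in WT and 44.3 Mb in AKO, a ratio of 0.736, while the ratio of tags was 0.981. The median peak was 565 bp wide in WT and 511 bp wide in AKO. The median fold enrichment over input, a value the authors' peak caller gives for each peak, was 4.94 in WT and 4.65 in AKO. A median WT peak rested on 19 overlapping fragments at its summit and a median AKO peak on 18. The smallest called summit held 10 fragments in either list, so sites with fewer fragments were not detectable at this depth. When each list was cut, from its strongest peak down, to the same covered length (50% of that of the AKO list), the ratio of peak numbers was 1.64. The AKO peaks kept were narrower on average than the WT peaks kept, and the cut reached further down the AKO list. This ratio therefore depends on the cut and does not measure the difference in width over the full lists. With only peaks of −log10 q of at least 5, the ratios were 0.583 for peak number and 0.548 for covered length.

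Most of the strongest sites were marked in both genotypes, and the sites called in a single library were mainly weak ones. Of the WT peaks, 60.4% overlapped an AKO peak by at least 1 bp (Wilson 95% interval 60.1 to 60.8), and of the AKO peaks 76.2% overlapped a WT peak (75.8 to 76.5). Peaks moved at random along their own chromosomes gave means of 3.70% and 4.37% over 100 shifts. A partner was found for 98.8% of the strongest 10% of WT peaks and for 30.5% of the weakest 10%. The same shares among AKO peaks were 99.2% and 56.2%. Merging the lists gave 84384 regions on chromosomes 1 to 19 and X, of which 41022 were marked in both libraries, 28501 in WT only and 14861 in AKO only. Within the 41022 shared regions the median pileup, which the authors scaled to the tag number of the input in both libraries, was 14.6 in WT and 12.3 in AKO. The AKO pileup was the lower one in 71.8% of them. The median AKO to WT ratio of pileup was 0.858 over all shared regions and 0.764 in the fifth of regions with the highest pileup.

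**Figure D1:**
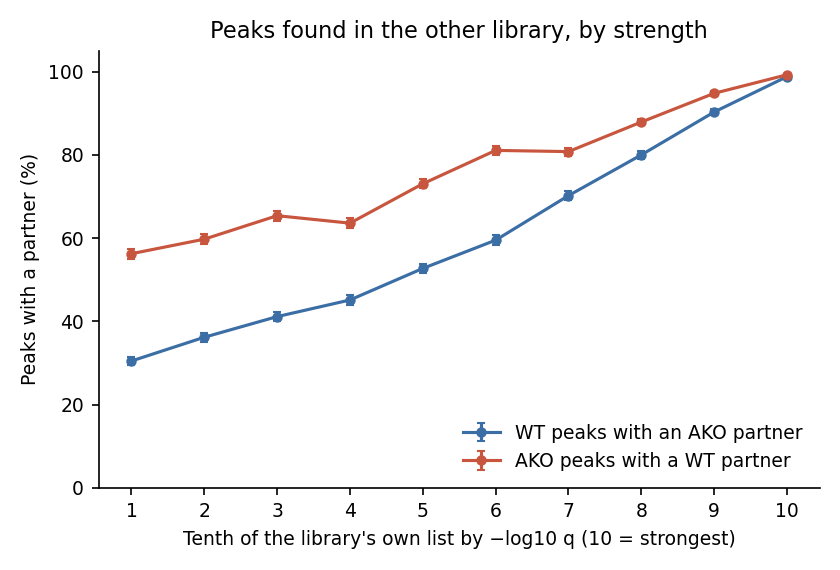
Share of peaks (%, y axis) that overlap a peak of the other library by at least 1 bp, in 10 equal groups of each library's own list ranked on −log10 q (x axis, 10 is the strongest); bars are Wilson 95% intervals, which cover counting error only. The share goes from 30.5% to 98.8% for WT peaks and from 56.2% to 99.2% for AKO peaks.

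Sites marked in a single library differed in where they lay. Among the 28501 WT-only peaks, 10.6% had their midpoint within 1 kb of either end of a protein-coding gene (10.3 to 10.998), against 3.35% of the 14861 AKO-only peaks (3.07 to 3.65) and 9.14% of the WT peaks with a partner. The interior of genes held 56.2% of WT-only and 64.5% of AKO-only peaks. Sites more than 10 kb from a protein-coding gene made up 23.7% and 24.9%. The WT peak with the highest −log10 q among those over 1 kb from any AKO peak lay inside Adamts3, a procollagen protease gene, at chromosome 5, 89882151 to 89883800 (mm10), with 47 fragments at its summit and a fold enrichment of 8.95. The next 4 lay near Fem1c, 39.0 kb away (chromosome 18, 46465343 to 46465932), inside Cyth4 (chromosome 15, 78610874 to 78611712), near Mdfi, 7.40 kb away (chromosome 17, 47841549 to 47842633), and inside the potassium channel gene Kcnc1 (chromosome 7, 46395939 to 46397035). The strongest AKO peak over 1 kb from any WT peak lay inside Calu, a gene for a calcium-binding protein of the secretory pathway, at chromosome 6, 29359387 to 29360375, with 30 fragments and a fold enrichment of 8.59. The next 4 had 27 fragments each and lay inside Dock4 (chromosome 12, 40788212 to 40788597), Susd6 (chromosome 12, 80807423 to 80808119) and Pknox2 (chromosome 9, 37086193 to 37086545), and 207 kb from Aebp2 (chromosome 6, 140884773 to 140885313).

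The second comparison, which the series description names as its aim, concerns the beige thermogenic genes. Coverage below is the length of peaks within a gene body and the 10 kb on either side of it. Lonp1 (chromosome 17, 56614297 to 56626903) had 8.75 kb and 6.21 kb. The position of the deleted part of Lonp1 is not given in the sources used here, so these peaks do not check the knockout. Of 14 genes named before the data were examined, 11 had less coverage in AKO, 2 had more and 1 had no peak in either library. With the full lists none of the 14 was lower by the rule of size, which asks for a WT to AKO ratio above 2 and a difference of at least 2 kb. Cidea and Ppargc1a met it with −log10 q of at least 5, with a fold enrichment of at least 4 and with equal numbers of peaks, and Elovl3 with −log10 q of at least 5. Prdm16 (chromosome 4, 154316122 to 154637360), a transcriptional regulator of brown and beige fat identity, had 17.8 kb in WT and 10.8 kb in AKO. Ebf2 (chromosome 14, 67233292 to 67430952), a transcription factor of brown fat precursors, had 12.3 kb and 7.79 kb. Ppargc1a (chromosome 5, 51454249 to 52115853), a coactivator of mitochondrial biogenesis, had 5.93 kb and 3.38 kb, and the fragments at its highest summit numbered 53 and 37. Cidea (chromosome 18, 67343564 to 67367794), a lipid droplet protein of brown and beige fat, had 4.73 kb and 3.23 kb, with 43 and 24 fragments at the highest summit. Adrb3 (chromosome 8, 27225776 to 27230845), the beta-3 adrenergic receptor, had 3.18 kb and 1.84 kb. Elovl3 (chromosome 19, 46131897 to 46135694), a fatty acid elongase induced by cold, had 2.66 kb and 1.48 kb.

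Ucp1 (chromosome 8, 83290348 to 83298456), the uncoupling protein of thermogenic fat, carried a single weak peak in each library at the lower-coordinate end of the gene. It spanned 83290005 to 83290522 with 16 fragments in WT and 83290248 to 83290582 with 14 fragments in AKO, so a difference at Ucp1 was not detectable at this depth. Dio2 (chromosome 12, 90724552 to 90739038), the deiodinase that activates thyroid hormone, had no peak in either library. Cox7a1 (chromosome 7, 30184171 to 30186030), a subunit of cytochrome oxidase, had 1.58 kb in WT and 1.90 kb in AKO. The fragments at its highest summit numbered 34 in WT and 18 in AKO, so length and height differed in opposite directions. Among adipocyte genes, Pparg (chromosome 6, 115360879 to 115490404), the master regulator of fat cell differentiation, had 3.75 kb and 2.502 kb. Adipoq (chromosome 16, 23146536 to 23157968), encoding adiponectin, had 0.995 kb and 1.31 kb, with 26 and 42 fragments at the highest summit. Fabp4 (chromosome 3, 10204342 to 10208616) had 1.34 kb and 0.901 kb, and Lep (chromosome 6, 29060221 to 29073876), encoding leptin, 1.38 kb and 0.293 kb.

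**Figure D2:**
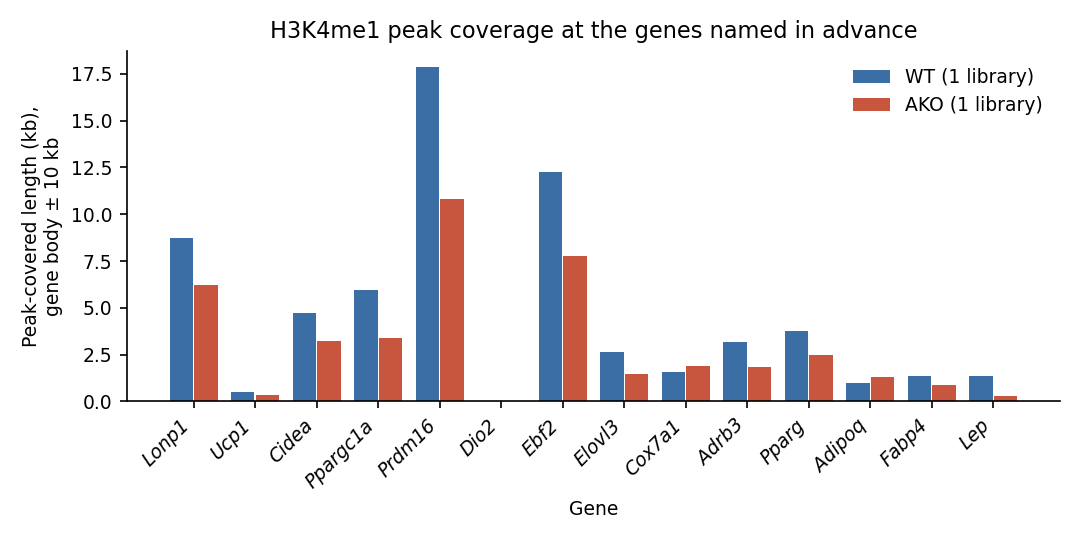
Peak-covered length (kb, y axis) within the gene body and 10 kb on either side for the 14 genes named in advance (x axis), 1 library per genotype and therefore no error bars. AKO has the shorter bar at 11 genes, the longer one at Cox7a1 and Adipoq, and neither library has a peak at Dio2.

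The thermogenic list of 47 genes had less coverage in AKO as a group. Coverage was lower in AKO for 41 members, higher for 4 and absent from both libraries for 2. Over all 21631 protein-coding genes it was lower for 11696, higher for 3226 and absent from both for 6707. The summed coverage of the list was 229 kb in WT and 146 kb in AKO, a ratio of 0.635 against 0.724 over all protein-coding genes. A ratio below 0.724 was not particular to this list. Most of the 18 lists had one, the other-tissue control list (0.606) among them, but not the matrix, housekeeping and lipolysis lists. The rule of size can call a gene lower only if it has at least 2 kb in WT, and with the full lists it called 1158 of 8217 such protein-coding genes lower. In the thermogenic list it called 5 members lower and none higher. Members with less than 2 kb in WT could not be called lower, and the count was not tested against the rate over all genes. It does not show that members of this list were called more often than other genes. The 5 were Kcnk3, a potassium channel gene used as a marker of thermogenic fat (12.3 and 5.40 kb), Acot11, an acyl-CoA thioesterase induced by cold (10.9 and 4.58 kb), Tbx1, a marker of beige precursors (5.84 and 2.03 kb), Slc36a2, an amino acid transporter on the surface of brown adipocytes (4.18 and 1.11 kb), and Eva1a (3.02 and 0.903 kb). The list was fixed by gene symbol. Whether each member, Eva1a among them, acts in thermogenic fat was not checked here. At Kcnk3 (chromosome 5, 30588170 to 30625270), 5 of the 12 WT peaks overlapped an AKO peak and all 6 AKO peaks overlapped a WT peak. Tnfrsf9 had the largest excess of the list, 0.727 kb in AKO from 1 peak of 13 fragments and none in WT. The list's median difference, −1.19 kb, lay at the 3.22nd percentile of 10000 random gene lists of the same size matched on coverage. It lay at the 9.46th percentile with peaks within 1 kb joined and at the 7.64th with gene bodies alone. With both lists limited to the same covered length, 17 members showed no difference, 23 had less and 7 more coverage in AKO, and the rule of size called only Slc27a1 and Acot11 lower. The summed ratio of the list was then 0.777 against 0.935 over all protein-coding genes, and ties fixed the median difference at 0.00 kb, so its percentile does not rank the list. The rule of size called 9 members lower with −log10 q of at least 5, 8 with a fold enrichment of at least 4 and 10 with peaks within 1 kb joined. Acot11 was among them in each of these settings, while Kcnk3, Slc36a2 and Eva1a were not with −log10 q of at least 5 or with equal numbers of peaks. Over all genes the rule also called more genes lower in stricter settings, 2385 with −log10 q of at least 5 and 1462 with a fold enrichment of at least 4.

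**Figure D3:**
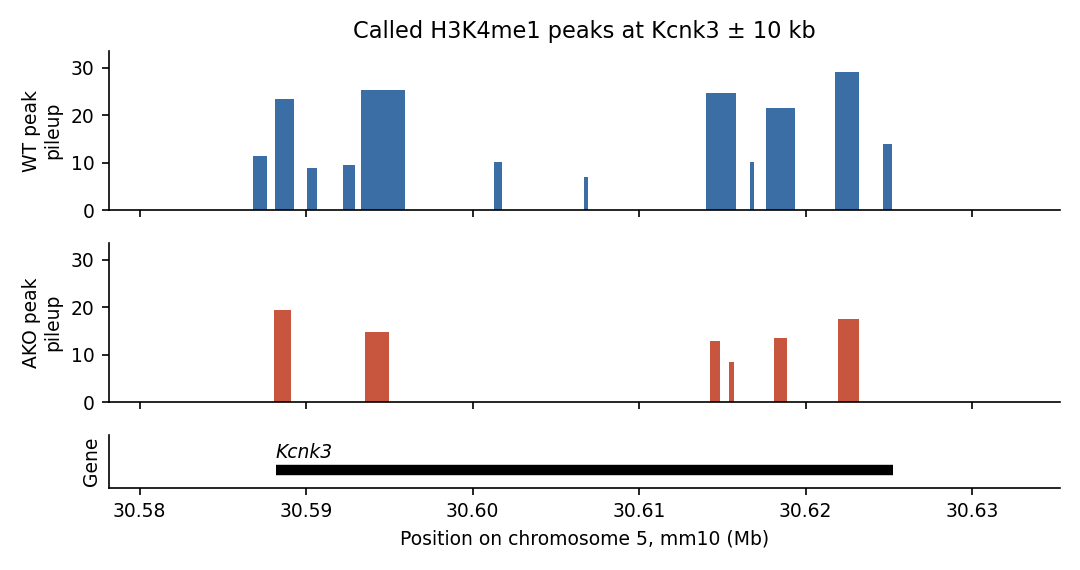
Called H3K4me1 peaks at Kcnk3 and 10 kb on either side (x axis, position on chromosome 5 in Mb, mm10); each bar spans a called peak and its height is the pileup at the summit, scaled by the authors to the input's tag number (y axis). WT has 12 peaks and AKO has 6, and every AKO peak lies on a WT peak.

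Genes of fat storage and mitochondrial metabolism were compared as lists fixed in advance. Among 40 genes of adipocyte identity and lipid storage, coverage was less in AKO for 34, and 6 were lower by the rule of size. They were Dgat2 (4.94 and 2.18 kb), Nr1h3 (4.97 and 1.201 kb), Gpd1, a glycerol phosphate dehydrogenase (8.14 and 0.939 kb), Fasn, the fatty acid synthase (7.45 and 2.93 kb), Aqp7, the glycerol channel (6.70 and 2.38 kb), and Plin1, which coats lipid droplets (3.67 and 1.43 kb). Srebf1, a regulator of lipid synthesis, had the largest difference of this list (24.96 and 14.6 kb) and Irs1 the largest excess in AKO (2.64 and 3.32 kb). The list lay at the 9.68th percentile. The 20 genes of fatty acid oxidation lay at the 28.7th percentile with Etfb lower by the rule of size (5.97 and 1.53 kb), and ranged from Cpt1a (17.6 and 11.6 kb) to Decr1 (0.775 and 1.51 kb). That placing was not stable, at the 95.5th percentile with −log10 q of at least 5 and the 72.6th with equal numbers of peaks, where the median was 0.00 kb. The 28 oxidative phosphorylation genes lay at the 17.5th percentile, but at the 0.750th with −log10 q of at least 5 and the 62.3rd with equal numbers of peaks. Ndufs3 and Atp5b were lower by the rule, and the list ranged from Ndufs7 (9.29 and 5.14 kb) to Atp5c1 (3.62 and 5.19 kb). Among 30 genes of the TCA cycle and of succinate and alpha-ketoglutarate metabolism, 17 had less and 9 more coverage in AKO, and Slc25a10 was lower by the rule. This list had the highest percentile, 93.1, and its largest excess in AKO was at Aco1 (3.58 and 4.22 kb). The 28 genes of mitochondrial proteostasis and biogenesis lay at the 45.7th percentile, with the largest excess in AKO at Hspa9 (no WT peak and 1.18 kb). The 23 genes of lipolysis and adrenergic signalling lay at the 13.8th percentile, but at the 75.99th with −log10 q of at least 5, the 67.9th with a fold enrichment of at least 4 and the 86.4th with equal numbers of peaks. Adcy6 was lower by the rule (11.4 and 5.45 kb), with Mgll (26.5 and 15.5 kb) at the low end and Pde4d (7.98 and 14.9 kb) at the high end.

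Markers of other cells of adipose tissue were also less covered in AKO. The summed ratio was 0.553 for 26 macrophage and monocyte markers (5.05th percentile), 0.548 for 23 lymphocyte markers (1.01st percentile) and 0.562 for 19 endothelial markers (10.7th percentile), below the 0.635 of the thermogenic list. Named members were Mertk, a receptor for engulfing dead cells (7.18 and 2.97 kb), Il2rb, a receptor chain for interleukin 2 (8.68 and 2.23 kb), and Eng (13.6 and 9.68 kb). The rule of size called 1 macrophage gene lower (Mertk), 2 lymphocyte genes (Il2rb and Cd4) and 4 endothelial genes (Kdr, Egfl7, Vwf and Esam). The endothelial list lay at the 1.61st percentile with −log10 q of at least 5, the 1.02nd with a fold enrichment of at least 4 and the 0.375th with equal numbers of peaks. With peaks of −log10 q of at least 5 the median difference of the lymphocyte list was 0.00 kb, with 47.8% of its members less covered in AKO. The macrophage list also had a median of 0.00 kb in that setting, with 38.5% of its members less covered in AKO. It lay at the 15.5th percentile with a fold enrichment of at least 4. Csf3r (0.533 and 0.911 kb) and Emcn (0.847 and 1.29 kb) had more coverage in AKO, and Ptprc had no peak in either library. The 22 inflammatory and interferon genes lay at the 9.08th percentile with Icam1 and Isg15 lower by the rule, from Socs3 (13.1 and 7.44 kb) to Cxcl1 (0.413 and 0.820 kb). The 22 progenitor and fibroblast markers lay at the 34.2nd percentile with Ly6a, Icam1, Gata2 and Gata3 lower by the rule, from Zfp423 (52.7 and 29.3 kb) to Zfp521 (10.8 and 11.8 kb). The 28 extracellular matrix genes had a summed ratio of 0.776 at the 10.1st percentile, with Col1a1, Eln and Bgn lower by the rule. That placing was not stable, since the list lay at the 63.4th percentile on chromosomes 1 to 19 alone, at the 78.1st without the 0.1% of peaks with the highest pileup, and at the 71.6th and 78.0th with −log10 q of at least 5 and a fold enrichment of at least 4. Smad3, which relays TGF-beta signals, had 55.7 and 43.9 kb, and Fbn1, encoding fibrillin, 19.7 and 24.2 kb. The 17 skeletal muscle markers had the lowest summed ratio, 0.516, at the 50.8th percentile with Acta1, Des, Tnnt3, Tnni2 and Pax7 lower by the rule, from Acta1 (6.26 and 2.87 kb) to Mef2c (no WT peak and 0.399 kb).

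The control lists also had less coverage in AKO. Over 28 genes of other tissues the summed ratio was 0.606 at the 5.47th percentile with Sox1, Olig2 and Nkx2-5 lower by the rule, from Sox1 (4.34 and 1.35 kb) to Vil1 (0.318 and 0.330 kb), and over 18 housekeeping genes it was 0.768 at the 55.7th percentile, from Gapdh, which was lower by the rule (5.08 and 2.097 kb), to Ywhaz (4.33 and 5.42 kb). The 26 genes of the integrated stress response lay at the 58.1st percentile, with Sesn2, Gdf15 and Ppp1r15a lower by the rule. They held Slc7a5 (17.0 and 11.7 kb) and Vldlr, the receptor for very low density lipoprotein (1.51 and 3.62 kb), which was the single gene over all lists that was higher by the rule of size. The 29 histone methylation and 2-oxoglutarate-dependent enzyme genes lay at the 52.5th percentile with Kmt2b and Kmt2d lower by the rule, from Kdm4b (27.4 and 17.6 kb) to Kmt2a (4.32 and 4.77 kb). Their percentile was 2.015 with equal numbers of peaks, 9.825 with −log10 q of at least 5 and 31.3 with a fold enrichment of at least 4. All 18 lists had a summed ratio below 1, between 0.516 and 0.776, and 2 of them, the thermogenic and the lymphocyte list, lay below the 5th percentile and none above the 95th. By chance 1.8 lists would lie outside these bounds if percentiles were evenly spread and independent. That does not hold here, since some lists share genes. For the macrophage, lymphocyte and other-tissue lists the median and the upper bound of the random lists were both 0 kb. The number 1.8 is therefore only a rough guide. With random lists matched on gene density as well, a choice made after seeing the data, 3 lists lay below the 5th percentile, the thermogenic (2.19), the lymphocyte (0.910) and the other-tissue control list (4.70), and the TCA cycle list lay above the 95th (95.3). Of the lists between these bounds as reported, only that of mitochondrial proteostasis stayed between them under every alternative setting, and each of the others passed a bound under at least 1.

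**Figure D4:**
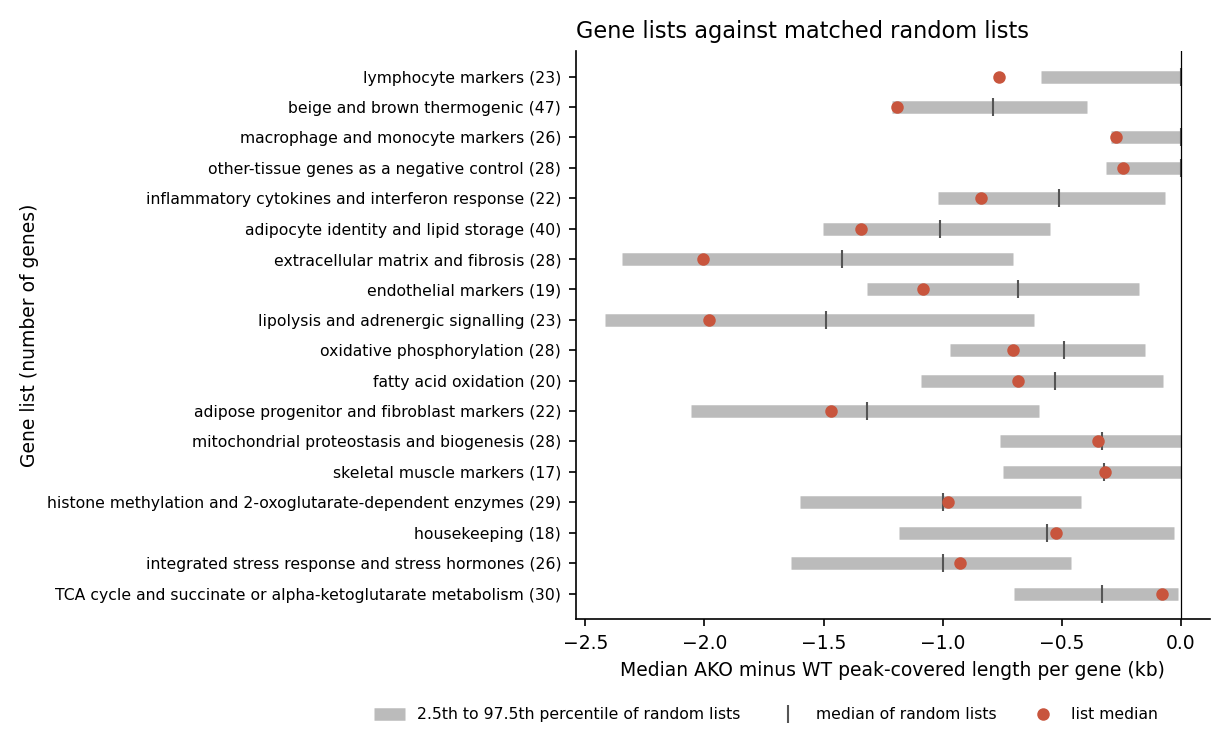
Median AKO minus WT peak-covered length per gene (kb, x axis) for the 18 gene lists fixed in advance (y axis, number of genes in brackets); red points are the lists, grey bars the central 95% of 10000 random lists matched on coverage and ticks their median. The lymphocyte list lies outside its bar on the low side, the thermogenic list at its lower end, and the TCA cycle list near its upper end.

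Across all 21631 protein-coding genes on chromosomes 1 to 19 and X, 11696 had less coverage in AKO, 3226 had more and 6707 had no peak in either library. The rule of size called 1158 genes lower and 49 higher in AKO. The largest differences in length were at long genes with many peaks, and none of the genes named for them below met the rule of size. Gse1 (chromosome 8, 120228501 to 120581383) had 166 kb in WT and 109 kb in AKO, and Agap1 (chromosome 1, 89454811 to 89895282) had 76.7 and 43.3 kb. Prkce, a protein kinase C gene (chromosome 17, 86167785 to 86657919), had 60.1 and 31.3 kb. The next were Tns1 (147 and 119 kb), Zfp469 (103 and 75.5 kb), Nav1 (70.2 and 42.8 kb), Cmip (79.4 and 52.7 kb), Prkag2, a regulatory subunit of AMP-activated kinase (69.9 and 43.8 kb), Chst11 (66.1 and 40.1 kb) and Zfhx3 (56.7 and 31.5 kb). The AKO to WT ratio was 0.810 at Tns1 and 0.731 at Zfp469, above the 0.724 over all protein-coding genes, and below 0.724 at the others named here.

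In the other direction, Egfr, the epidermal growth factor receptor gene (chromosome 11, 16752203 to 16913907), had 17.8 kb in WT and 30.0 kb in AKO. Maml2, a Notch coactivator gene (chromosome 9, 13296561 to 13709533), had 24.2 and 35.7 kb, and Adamts12, an extracellular protease gene (chromosome 15, 11064773 to 11349232), had 8.98 and 16.9 kb. Other large excesses were at Lpp, a focal adhesion gene (46.1 and 53.9 kb), Pde4d, a cyclic AMP phosphodiesterase gene (7.98 and 14.9 kb), Rbms1 (16.2 and 23.0 kb), Cdk14 (8.11 and 14.4 kb), Ext1 (23.8 and 30.1 kb) and Gnaq (16.1 and 21.9 kb). These genes with an excess did not meet the rule of size either. Windows of neighbouring genes overlap, so gene counts are not counts of independent sites. With the lists limited to the same covered length, the rule of size called 533 genes lower and 465 higher, which is 53.4% lower against 95.9% of calls with the full lists. That cut makes the total covered length equal in both lists. A near balance of calls over all genes follows from the cut and says nothing about the size of the deficit.

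The deficit was not spread evenly over the genome. Over 435 bins of 5 Mb on chromosomes 1 to 19, the AKO to WT ratio of covered length was 0.867 (bootstrap 95% interval 0.834 to 0.902) in the fifth of bins with the fewest protein-coding genes and 0.688 (0.680 to 0.698) in the fifth with the most. Chromosome 17 had the lowest ratio among these chromosomes, 0.699, and chromosome 3 the highest, 0.816. On the X chromosome the ratio was 0.339, with 390 WT peaks and 161 AKO peaks. Of the X-linked WT peaks 25.4% overlapped an AKO peak (21.3 to 29.9), against 58.5% to 61.9% on the other chromosomes.

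**Figure D5:**
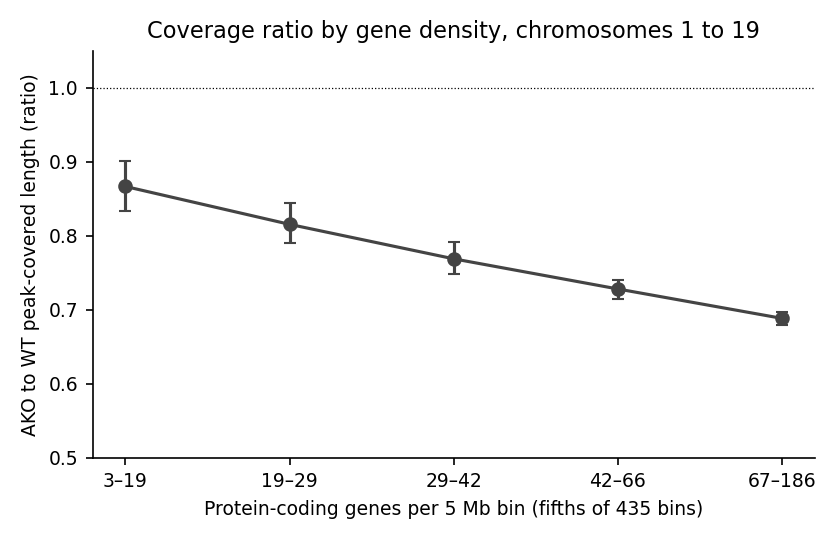
Ratio of AKO to WT peak-covered length (y axis, which starts at 0.5) in 5 equal groups of 5 Mb bins of chromosomes 1 to 19 by their number of protein-coding genes (x axis); bars are bootstrap 95% intervals over bins within these libraries. The ratio goes from 0.867 in the bins with the fewest genes to 0.688 in those with the most.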

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

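When each list was taken from its strongest peak down to the same covered length, which also keeps only stronger peaks, the AKO to WT ratio of peak number was 1.643 in place of 0.866. The AKO peaks kept were narrower on average, and the cut reached further down the AKO list. The WT and AKO shares of shared peaks were 72.65% and 50.07%. Genes lower and higher in AKO then numbered 533 and 465, and 48.94% of thermogenic genes had less coverage in AKO in place of 87.2%, with 17 of 47 tied. Their summed ratio was 0.777 against 0.935 over all genes. Because this cut sets the total covered length equal, a near balance of lower and higher genes over the genome follows from it. The thermogenic list lay at the 50.05th percentile, a value that ties at 0 kb give, within 0.1, to 10 of the 18 lists and that does not rank them. With the same number of peaks in each list the shares were 61.17% and 67.53%, with 110 higher genes.

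With −log10 q of at least 5, the shares of shared peaks were 44.18% (WT) and 80.54% (AKO), and 2385 genes were lower and 16 higher. WT-only peaks at a gene end and far from genes were then 11.8% and 21.46%, and AKO-only peaks 3.661% and 21.18%. With a fold enrichment of at least 4 the shares were 56.94% and 73.4%. Joining peaks within 1 kb gave a WT share of 63.86%, 128 higher genes and a thermogenic percentile of 9.455. Shares were 48.04% and 69.1% when at least 50% of the peak had to be covered, 38.66% and 44.67% for reciprocal overlap of 50%, and 73.16% and 84.71% for a partner within 1 kb. At 2.5 kb around a gene end the WT-only and AKO-only shares were 20.51% and 11.29%. A rule of 1.5-fold and 1 kb gave 4324 lower and 369 higher genes, and all annotated genes gave 1765 lower. Gene bodies alone, an alternative chosen after seeing the data, gave 527 lower genes and a thermogenic percentile of 7.64. The lymphocyte list, at the 1.01st percentile, lay at the 75.97th with −log10 q of at least 5, where its median was tied at 0.00 kb and 47.83% of its members had less coverage in AKO. Matching on gene density too, also chosen after seeing the data, put the other-tissue list at the 4.7th percentile and the TCA cycle list at the 95.26th. The causes of the other shifts were not tested. Among the other lists' values, 295 shares and percentiles stayed within their interval or within the same bounds of 5 and 95, which does not keep a list on its side of the random median, 38 shares moved beyond their interval, 35 percentiles passed the 5th or 95th percentile anew and 5 no longer did, apart from the lymphocyte value named above.

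The windows around 5′ ends, the motif alternatives and their summit version were not run, because strand and sequence were not used here. No paired analysis was possible because each genotype has 1 library and the labels carry no replicate numbers. With 15015805 and 14733950 tags and a smallest callable summit of 10 fragments, weak sites such as the one at Ucp1 cannot be compared.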

Other observations

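The gene sets below and the tests of the X chromosome were chosen after the values had been seen. Among the genes lower in AKO by the rule of size, Hoxb3, a homeobox gene, had 18.0 kb of coverage in WT and 6.79 kb in AKO, Hoxa3 had 11.3 and 4.01 kb, and Notch1, a receptor of cell-cell signalling, had 20.9 and 9.45 kb. Hoxc9 and Hoxc10, both of the thermogenic list, did not meet the rule of size, with 2.65 and 0.701 kb at Hoxc9 and 2.04 and 0.544 kb at Hoxc10. The 49 genes higher in AKO included the adhesion and cytoskeleton genes Ctnnd1 (2.197 and 5.91 kb), Vcl, encoding vinculin (1.57 and 5.002 kb), Ctnna1 (0.900 and 3.06 kb) and Pdlim5 (2.18 and 5.16 kb), and the receptor genes Met (2.11 and 4.74 kb), Bmpr1a (0.326 and 3.63 kb) and Ghr, the growth hormone receptor (0.544 and 3.13 kb).

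A hypothesis from these genes is that focal adhesion, actin and YAP-TEAD genes carry relatively more H3K4me1 in the AKO library. A list of 40 such genes that left out every gene already seen among the higher ones was tested against random lists. Its summed coverage was 534 kb in WT and 479 kb in AKO, a ratio of 0.897 against 0.724 over all genes, and 28 members had less and 12 more coverage in AKO. The list's median lay at the 99.88th percentile of random lists matched on coverage and gene density, and at the 99.79th when matched on coverage and gene length. Coverage of these genes may thus differ less between the libraries than that of genes of similar coverage, and the cause was not tested.

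The smaller covered length in AKO is the main pattern of the series, and 1 library per genotype leaves the genotype and the library confounded. Fewer sequenced tags do not account for it, since the median height ratio in the 20% of shared regions with the highest pileup was 0.7643 after both libraries were scaled to the same tag number. A weaker enrichment of the whole AKO library, equal at every site, stays open for most of the deficit. Whether it could by itself give the larger deficit on the X chromosome at matched −log10 q described below was not tested. Matched on joint height, the median height ratio differed by −0.01788 between the most and the least gene-dense regions (bootstrap 95% interval −0.0323 to −0.0110). The interval is below 0 but the value is short of the bound of −0.03 set before the test, so neither outcome named in advance was met and the test cannot decide. The deficit covered housekeeping genes (0.768) and genes of other tissues (0.606) as well as thermogenic genes (0.635), and an effect of the genotype was not separable from it.

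The larger deficit in gene-dense regions was weighed separately. It does not appear to sit only at genes, because the rank correlation across 5 Mb bins of the covered-length ratio with gene density was −0.4316 over peaks more than 10 kb from any protein-coding gene (259 bins) and −0.544 over all peaks, across bins that are not independent replicates. A stronger signal in gene-dense regions, with strong peaks losing more length, cannot be told apart from an effect of density, because the AKO share of peak length was lower by over 1 percentage point in gene-dense regions in 4 of 5 height classes but by 0.571 points in the highest. Gene-dense regions are rich in G and C, so a difference in base composition between the libraries may also give this gradient and the 3.35% of AKO-only against 10.6% of WT-only peaks at gene ends. It was not tested, since no genome sequence was used here.

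The deficit of X-linked peaks goes beyond what their −log10 q predicts. X-linked peaks were few in both lists, 0.541% of WT and 0.258% of AKO peaks, and the matching below was on −log10 q and not on peak width. X-linked WT peaks had an AKO partner less often than other WT peaks of the same −log10 q, by 26.2 percentage points (difference −26.2, interval −29.9 to −22.1), while the difference for X-linked AKO peaks was −6.79 points (−14.2 to 0.218). These intervals do not overlap, the outcome named against X-linked peaks lying nearer the calling threshold as the whole cause. Matching used only the −log10 q measured in the peak's own library, a single noisy value, so the comparison cannot exclude that cause. The deficit was present in 3 of 3 parts of the chromosome, where 25.2%, 26.9% and 23.1% of WT peaks had an AKO partner against 50.6%, 52.8% and 50.8% of matched peaks elsewhere. A different dosage of the X chromosome in the animals behind the libraries, which the labels give as male in both, is consistent with that, and so are other differences between the libraries that act on the whole X chromosome.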
